A study of Cunninghamia lanceolata with 3 samples.

How the data were processed

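Single-cell RNA was measured in protoplasts of stem differentiating xylem of the conifer Cunninghamia lanceolata (Chinese fir), from 2-year-old wild-type plants of 1 line. Per the labels' protocols, debarked stem segments were digested with cell wall enzymes for about 2 h, the released protoplasts were passed through a 70 µm mesh, and 3 biological replicate libraries were made with 10x Genomics droplet chemistry that counts the 3' ends of polyadenylated RNA. The labels name a pair of kit generations without saying which library had which. Cell Ranger 7.1.0 is named in the submitters' processing notes. The genome build and the gene annotation are not given in the sources used here.

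The deposited values are counts of unique molecular identifiers (UMIs) per gene and cell barcode, 1 matrix per library, not normalized. The 3 matrices list the same 37225 gene IDs. The files do not pair these IDs with gene names, so the gene lists and cell type markers chosen before the data were examined could not be used, clusters go by number, and gene IDs are printed as given. Every deposited barcode had at least 500 UMIs and at least 200 genes, so the filter at these values removed 0 barcodes. The 3 libraries held 13933520, 4513499 and 2245069 UMIs. The number of UMIs per gene sets the precision of each value, and exact (Clopper-Pearson) 95% intervals of shares cover counting error only.

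Each UMI was assigned at random, with probability 0.5, to a clustering set or to a held-back set, so that gene values were not read from the molecules that made the clusters. In the clustering set, cells were scaled to the median depth and log-transformed, 2000 variable genes were chosen within libraries among genes seen in at least 10 cells, values were centred and scaled within each library and limited to 10 SD, and 30 principal components were taken (scanpy 1.11.5, numpy 2.4.6, Python 3.11.15). Leiden clustering at resolution 0.5 (leidenalg 0.10.2) used the shared-neighbour graph of the 20 nearest neighbours. Clusters are numbered by size. Clusters with at least 20 cells in each of the 3 libraries entered an average-linkage tree on 1 minus the Pearson correlation of log2(CPM + 1), where CPM is the UMI count of a gene scaled by the total of its sum, and the first split of the tree defined 2 branches.

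Gene tests used held-back UMIs summed per library and cluster, or per library and branch, in sums of at least 20 cells. Cells are not replicates, and the library was the replicate. The edgeR 4.0.16 quasi-likelihood test (R 4.3.3) was fitted with TMM normalization, the filterByExpr filter on low counts and the library as a block, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Each cluster was compared with the mean of the other clusters in 1 fit over all sums, and branch a with branch b in a fit of 6 sums. Sums from the same library come from its cells alone and share its preparation, which is the source of the pairing. On the log2(CPM + 5) scale, their deviations from the branch means correlated at 0.569, 0.509 and 0.590 across genes within libraries 1, 2 and 3, which is why the library was kept as the block. Between different libraries the correlation was at most -0.014. Deviations from a mean over the libraries cancel out, so positive values within libraries push those between libraries down. Standard errors were computed from the fold change and the F statistic. Clusters 10 and 11 had 1 sum of at least 20 cells and cluster 9 had 2. A lone sum was taken to vary like those of the other clusters.

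Named genes were chosen by a rule set before the data were examined. They had to pass the threshold, lie on the same side in the 3 libraries and reach a mean of at least 50 CPM on the higher side, and were ranked by the size of the log2 fold change. The first 2 higher and 2 lower in the branch comparison and the first 2 higher in each cluster are printed. CPM printed for the other clusters are plain means over all of them in each library, sums under 20 cells included. The fit averages the other clusters on the log scale, from sums of at least 20 cells. The ratio of printed CPM values therefore need not match the fold change. Genes per cell were counted after thinning each cell to 1000 UMIs, with shallower cells left out. Neighbours were also found in a space built from held-back UMIs alone, and the nearest cluster of each cluster was found from held-back UMIs on the log2(CPM + 20) scale. The neighbour comparisons and the pairwise tests between clusters were chosen after seeing the data. Library agreement was computed over genes with at least 10 UMIs in the 3 libraries together.

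Doublets were scored with Scrublet. Its automatic threshold marked 2 of 6961 cells, too few to be taken as working, so no cell was removed, and removal of the 172 highest scores, at 0.8% per 1000 barcodes, was tried as an alternative. The other alternatives were all UMIs for clustering and testing, resolutions 0.3 and 0.8, 15 components, scaling that ignored libraries, anchor integration with Seurat 5.3.0, a minimum of 1000 UMIs, no filter on cells, another random assignment of UMIs, each library left out, no block, DESeq2 1.42.0 size factors or its Wald test, no filter on low counts, a 1.5-fold threshold, complete linkage, other thinning depths and other pseudocounts. Clusters were compared between settings only where their overlap (Jaccard index) was over 0.5.

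The tests were tested on simulated data with 200 changed genes, raised and lowered in equal number, and no other difference between clusters. In the real data, 43.1% of the genes tested were called between the branches and 55.0% in cluster 6. The false-call rates of the simulations therefore do not cover changes so wide, or the scaling under them. For the branch comparison, 42% of the genes changed 2-fold and 92% of those changed 4-fold were recovered among 11789 genes, and 5.63% of the calls were false. For cluster 1, 18% and 75% were recovered among 12558 genes with 8.82% false calls, for cluster 4, 33% and 67% with 9.09%, and for cluster 8, 2% and 40% with 4.55%. For cluster 9, 7% and 50% were recovered with 5% false calls, and for cluster 11, 1% and 10% with 0 false calls. When cells simulated from 1 population were clustered and tested on held-back UMIs, edgeR called 0 of 12162 genes, and at most 575 had an unadjusted p under 0.05. These cells were drawn from the mean profile of their library and differed only in depth and by counting. Their held-back UMIs were therefore independent of the clusters, so the lack of calls could be foreseen. A population whose cells vary gradually was not simulated. With all UMIs used for both steps, edgeR called 0 of 14171 genes, with at most 695 at an unadjusted p under 0.05, so this simulation does not show that holding back UMIs mattered.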

Results

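The data collected were UMI counts of single protoplasts from differentiating xylem, the layer inside the bark in which new wood cells form. There was 1 group of 3 biological replicate libraries, so no treatment or genotype was compared. The study's title concerns how the developmental complexity of xylem differs among seed plants, and the comparisons possible here are between cell populations within this conifer. Libraries 1, 2 and 3 held 4194, 1542 and 1225 cells with medians of 1289.5, 1247 and 1219 UMIs per cell. UMIs were found for 23576, 21000 and 19971 genes, of which 18847 were detected in every library.

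The summed profiles of the 3 libraries were close but not identical. Across 19246 genes, the Pearson correlation of log2(CPM + 1) was 0.951 between libraries 1 and 2, 0.921 between 1 and 3, and 0.922 between 2 and 3, where genes are not independent replicates. Between 12.6% and 22.6% of the genes differed by more than 2-fold in a pair of libraries. The chi-square statistic per degree of freedom lay between 32.2 and 46.8 for the 3 pairs, so no pair looked like 1 library deposited under 2 names. The labels give the libraries as biological replicates.

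The cells fell into 11 clusters. Cluster 1 held 20.0% ± 9.37 of the cells of a library (SD, n = 3), cluster 2 held 12.2% ± 4.64, cluster 3 held 13.6% ± 5.68 and cluster 4 held 12.4% ± 6.86. Cluster 5 held 13.4% ± 7.12, cluster 6 held 12.1% ± 5.68, cluster 7 held 5.45% ± 2.15, cluster 8 held 4.41% ± 1.58 and cluster 9 held 4.04% ± 2.51. The 2 smallest clusters, 10 and 11, held 1.32% ± 0.422 and 1.15% ± 0.489. The shares of clusters 3 and 5 changed with the clustering, cluster 3 to 7.38% at resolution 0.8, 21.7% without high doublet scores and 21.5% at a minimum of 1000 UMIs, and cluster 5 to 21.1% with all UMIs, 20.7% without high doublet scores and 23.5% at that minimum. The composition of the libraries differed by more than counting error. Cluster 1 made up 30.8% of library 1 (exact 95% interval 29.4 to 32.3), 14.5% of library 2 (12.8 to 16.4) and 14.7% of library 3 (12.8 to 16.8). Cluster 4 made up 20.0% of library 3 but 10.5% of library 1 and 6.68% of library 2. Clustered alone, the libraries gave 10, 8 and 5 clusters, with adjusted Rand indices of 0.622, 0.411 and 0.441 against the joint clusters. In 9 other clusterings of the joined libraries, clusters 4, 7 and 9 had a match (Jaccard index over 0.5) in each, clusters 1, 3 and 2 in 6, 5 and 3, and cluster 6 in 1, and the adjusted Rand index with the main clusters lay between 0.354 and 0.716.

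**Figure D1:**
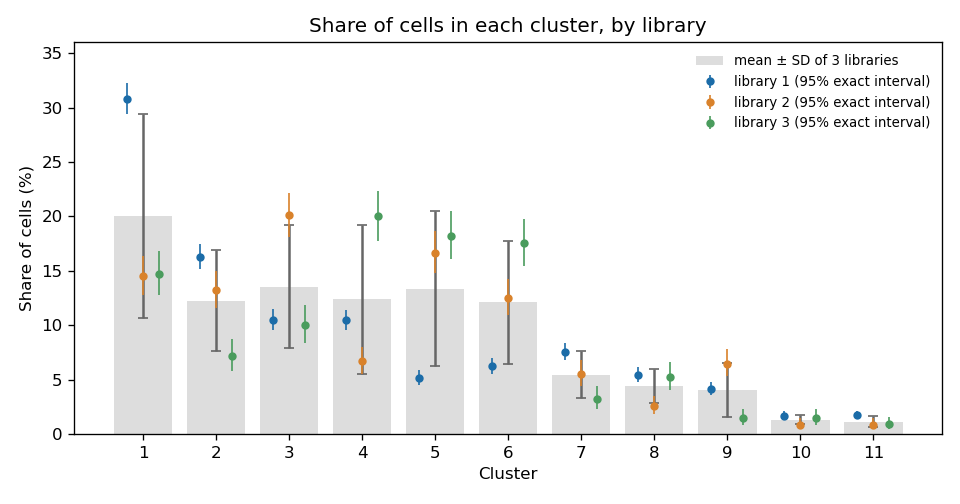
Share of cells (%, vertical axis) in each of the 11 clusters (horizontal axis), with points for libraries with exact 95% binomial intervals and grey bars for means with SD over 3 libraries. Cluster 1 makes up 30.8% of library 1 and under 15% of the other two.

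Cells of a cluster also lay near each other in molecules that had not been used to define it, a comparison chosen after seeing the data. In the held-back UMIs, 92.8% ± 2.69 (SD, n = 3) of the nearest neighbours of cluster 7 cells were cluster 7 cells, against a share of 6.35% of all cells. The corresponding values were 88.5% ± 4.32 for cluster 10 against 1.44%, 83.6% ± 2.06 for cluster 6 against 9.61%, and 79.0% ± 9.12 for cluster 5 against 10.0%. The lowest values were 51.5% ± 12.5 for cluster 11, 61.5% ± 6.38 for cluster 2 and 64.2% ± 3.37 for cluster 1. Clusters 7, 10, 6 and 5 were also the deepest, with pooled medians of 2166.5, 1971.5, 2643 and 2274 UMIs per cell. Clusters 11, 2 and 1 had medians of 791, 1170 and 914. The held-back UMIs of a cell share its depth, so cells grouped by depth could also lie near each other there. How far depth set these values was not tested.

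The clusters were parted at the first split of the cluster tree, which gives 2 branches in any data and does not test how many there are. Clusters 1, 2, 3, 4 and 8 formed branch a, with 62.6% ± 9.45 of the cells (SD, n = 3), and clusters 5, 6 and 7 formed branch b, with 30.9% ± 10.6. Branch b made up 19.0% of library 1, 34.7% of library 2 and 39.0% of library 3. Clusters 1, 2 and 3 were the most alike, with profile correlations of 0.922, 0.912 and 0.912 across genes. Clusters 5 and 6 correlated at 0.854, and cluster 5 also correlated at 0.838 with cluster 3, on the other side of the split. In the held-back UMIs, 96.2% ± 0.308 of the neighbours of branch a cells were in branch a and 90.9% ± 2.93 of those of branch b cells were in branch b. Cells of branch b were deeper, with a median of 2340 UMIs against 1071, a difference that the held-back UMIs share. With every cell thinned to 500 UMIs and the clusters kept, an alternative chosen after seeing the data, cluster 7 moved to branch a, and 93.2% of the cells stayed on their side. With the thinned cells clustered again, the split set apart 254 cells, 246 of them of cluster 6.

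**Figure D2:**
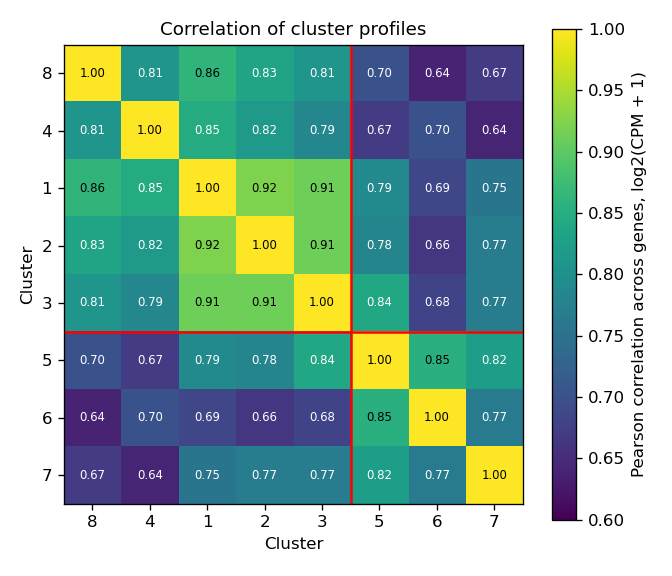
Pearson correlation across genes of log2(CPM + 1) between the 8 clusters with at least 20 cells in every library, from UMIs of the clustering set, where both axes are cluster numbers and red lines part branch a (clusters 8, 4, 1, 2 and 3) from branch b (clusters 5, 6 and 7). Clusters 1 and 2 correlate at 0.922 and clusters 6 and 8 at 0.638.

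The branches differed in a large part of the genes tested. Of 11789 genes tested, 2224 were higher in branch a and 2858 were lower, which together is 43.1% of the genes tested. Changes over 4-fold were mostly toward branch b, with 1472 genes lower in branch a by that much and 308 higher. Cula0021988 was higher in branch a by 3.85 ± 0.40 on the log2 scale (SE, adjusted p = 2.18e-06, edgeR), at 88.6 ± 28.8 CPM against 4.04 ± 4.59 (SD, n = 3), and Cula0030170 by 3.74 ± 0.46 (adjusted p = 1.23e-05, edgeR). Their sizes rest on library 1, since branch b held 31, 0 and 2 UMIs of the former and 33, 0 and 0 of the latter in libraries 1, 2 and 3. Without library 1 the fitted log2 fold changes were 5.48 and 8.58, and Cula0030170 was at 6.40 with the DESeq2 Wald test. Cula0006845 had a log2 fold change of -5.58 ± 0.39 (adjusted p = 9.19e-08, edgeR), at 4.53 ± 3.69 CPM in branch a against 124 ± 59.3 in branch b, and Cula0022685 one of -5.23 ± 0.36 (adjusted p = 8.58e-08, edgeR). Of the called genes, 4690 lay on the same side in the 3 libraries. Without the library block, 2860 genes were called, 835 higher and 2025 lower, and each was also called with it. Without library 1, 1150 of 10621 genes tested were higher in branch a and 2275 were lower. With the tree from cells at 500 UMIs, 4101 of the 5082 calls were made the same way and 143 the opposite way.

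Cluster 6 differed from the mean of the other clusters in 6912 of 12558 genes, 4981 of them higher, and cluster 4 in 5529 genes, 4171 of them higher. Cluster 7 differed in 3254 genes, 2296 of them higher. In pairwise edgeR tests among the 9 clusters with at least 2 sums, chosen after seeing the data, 717 genes were higher in cluster 6 than in each other cluster, 461 in cluster 7 and 176 in cluster 4. Cula0033495 was higher in cluster 7 by 7.45 ± 0.29 on the log2 scale (SE, adjusted p = 1.93e-36, edgeR), at 2678 ± 1752 CPM (SD, n = 3) against 36.6 ± 31.7, and Cula0000596 by 7.47 ± 0.47. The CPM after "against" is a plain mean of the other clusters, whereas the fit averages them on the log scale. Cula0005111 was higher in cluster 6 by 6.07 ± 0.36, at 147 ± 32.2 CPM against 6.41 ± 3.69, and Cula0006565 by 5.94 ± 0.48. Cula0011149 and Cula0014094 were higher in cluster 4 by 5.23 ± 0.59 and 4.98 ± 0.60. Against the summed rest of the cells, 46.7% of the cluster 6 calls, 49.1% of those of cluster 4 and 47.8% of those of cluster 7 were higher. With the mean of the other clusters the values were 72.1%, 75.4% and 70.6%, and with DESeq2 size factors 77.7%, 83.5% and 69.0%. The comparison with the summed rest was chosen after seeing the data. It also fitted each cluster separately with its own filter and scaling. Without library 1, 4522, 3045 and 1620 genes were called in clusters 6, 4 and 7, and 1817 in cluster 5. The log2 fold change of Cula0033495 was 9.19 without library 1 and 6.84 without library 2, and that of Cula0006565 was 5.32 without library 1.

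Clusters 1, 2, 3 and 8 differed from the mean of the other clusters in 957, 1314, 2098 and 876 genes, of which 780, 940, 1424 and 572 were higher. Against the summed rest the counts were 3627, 3439, 4842 and 1480, and 2234 in cluster 7. In clusters 1, 2, 3 and 8, 20, 20, 19 and 41 genes were higher than in each other cluster of the pairwise tests. Cula0036273 was higher in cluster 1 by 5.40 ± 0.63 on the log2 scale (SE, adjusted p = 3.48e-10, edgeR), from 29, 3 and 17 UMIs in libraries 1, 2 and 3. Its adjusted p was 0.164 with the DESeq2 Wald test. Cula0022625 was higher in cluster 1 by 4.71 ± 0.58. In held-back UMIs, Cula0036273 was seen in 2.12% and Cula0022625 in 2.83% of cluster 1 cells. Among the named genes such shares ran up to 68.1%, for Cula0033495 in cluster 7. Cula0006229 was higher in cluster 2 by 5.46 ± 0.40, at 282 ± 131 CPM (SD, n = 3) against 23.4 ± 16.9. Cula0012217 was higher there by 5.42 ± 0.52, from 71, 17 and 1 UMIs in libraries 1, 2 and 3. Cula0000396 was higher in cluster 3 by 3.98 ± 0.35, at 357 ± 417 CPM, and Cula0000958 by 4.43 ± 0.54. Cula0023266 was higher in cluster 8 by 6.79 ± 0.55, at 200 ± 57.5 CPM against 2.71 ± 3.27, and Cula0016088 by 6.00 ± 0.66. These values rest on 44, 3 and 5 UMIs of the former and 24, 4 and 3 of the latter in libraries 1, 2 and 3. Neither gene was tested without library 1. With DESeq2 size factors 63.9%, 57.4%, 45.7% and 75.2% of the calls of clusters 1, 2, 3 and 8 were higher, and against the summed rest 39.2%, 39.0%, 40.2% and 31.6%, where the main values were 81.5%, 71.5%, 67.9% and 65.3%. The counts were 298, 487, 1036 and 436 without the block and 280, 476, 939 and 238 without library 1, and cluster 1 had 596 without library 2. Without library 1, the log2 fold changes of Cula0022625, Cula0006229, Cula0012217 and Cula0000396 were 5.86, 6.21, 4.71 and 4.97.

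Cluster 5 differed in 2682 genes, 2348 of them higher. Cula0002890 was higher by 6.64 ± 0.48 on the log2 scale (SE, adjusted p = 4.64e-20, edgeR), at 88.7 ± 31.6 CPM (SD, n = 3) against 4.12 ± 4.23, with an adjusted p of 0.148 in the DESeq2 Wald test, and Cula0018258 was higher by 5.70 ± 0.48. In this cluster 136 genes were higher than in each other cluster. Of its calls 87.6% were higher with TMM, 77.4% with DESeq2 size factors and 56.5% against the summed rest.

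The 3 small clusters outside the tree also differed from the mean of the other clusters. Cluster 10, with 100 cells, entered the main fit with library 1 alone. Cula0016285 and Cula0000435 were higher in cluster 10 by 9.81 ± 0.36 and 9.71 ± 0.35 on the log2 scale (SE) in that fit. Over the 3 libraries, Cula0000435 stood at 1243 ± 234 CPM (SD, n = 3) against 1.61 ± 2.29 elsewhere. Cluster 9 differed in 807 genes, 598 of them higher, and 105 genes were higher in it than in each other cluster of the pairwise tests, which left out clusters 10 and 11. Cula0028229 was higher in it by 6.48 ± 0.41 and Cula0008133 by 6.34 ± 0.57. Libraries 1 and 2 held 57 and 54 UMIs of the former and 28 and 22 of the latter. Library 3, whose 18 cells of cluster 9 were left out of the fit, held 1 UMI of each. Cluster 11, with 96 cells, entered the main fit with library 1 alone. Cula0003313 was higher in cluster 11 by 7.12 ± 0.85 in that fit, from 16 UMIs in library 1. Libraries 2 and 3 held 4 and 1 UMIs of this gene, in sums left out of the fit. Cula0018103 was higher by 6.65 ± 0.35, at 2582 ± 3120 CPM over the 3 libraries. With sums of at least 10 cells, an alternative chosen after seeing the data, clusters 10 and 11 entered with 3 libraries each. In that fit 2339 and 224 genes were called for clusters 10 and 11, 59.2% and 63.4% of them higher. Cluster 9 had 448 calls without the block, 290 without library 1 and 431 without library 2.

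At equal depth, the most genes per cell were detected in cluster 4. RNA free in the droplets also adds to genes detected, and its share was not estimated. With each cell thinned to 1000 UMIs, a cluster 4 cell had 846 ± 11.4 genes (SD, n = 3), first of the 8 clusters of the tree in each library, and a cluster 8 cell had 787 ± 10.2, second in each library but from 114, 13 and 14 cells, with 190 left out. At 500 UMIs, which left out no cell, cluster 4 was still first in each library and cluster 8 had rank 4 in library 1. Clusters 3, 5 and 7 had 688 ± 32.4, 695 ± 37.7 and 679 ± 29.9 genes, below the mean of the 8 clusters in each library. Cells of branch b had 704 ± 4.85 genes and cells of branch a 755 ± 29.9, a difference of -51.0 ± 31.2 that was negative in 3 of 3 libraries. No exact permutation test was made, since its smallest two-sided p for 3 paired differences is 0.25. The order of the branches turned over without thinning, at 1840 ± 511 genes in branch b and 1034 ± 130 in branch a, since branch b cells were deeper. Cells under 1000 UMIs were left out, 2148 of branch a and 362 of branch b.

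**Figure D3:**
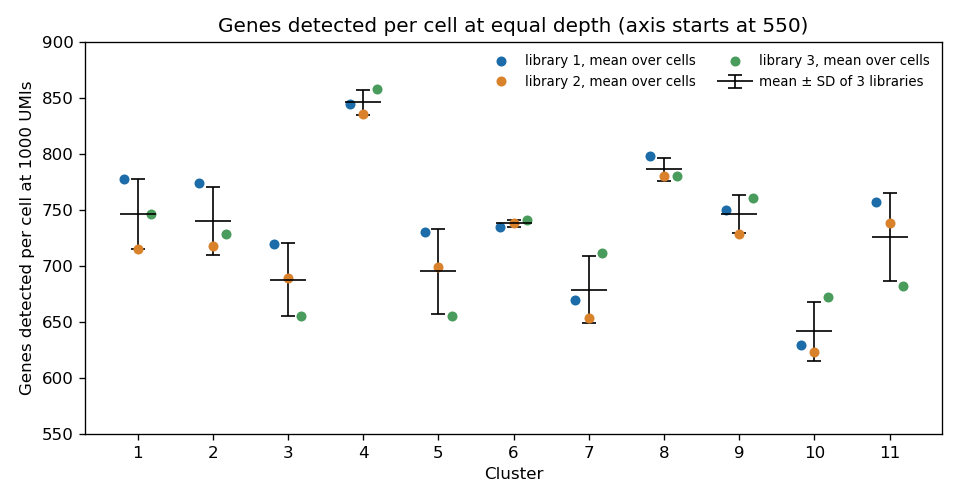
Genes detected per cell after thinning to 1000 UMIs (vertical axis, which starts at 550) in the 11 clusters (horizontal axis), with points for means over the cells of each library and black marks for means with SD over 3 libraries. Cluster 4, at 846, is highest in each library.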

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

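Tests with sums of at least 10 cells, against the summed rest, and with the trees of equally weighted or thinned cells were chosen after seeing the data. The number of clusters lay between 8 and 13 under 10 alternatives, but clusters 5, 8 and 10 had no match in 2 of 9 other clusterings, clusters 1 and 11 in 3, cluster 3 in 4, cluster 2 in 6 and cluster 6 in 8. The share of cells in branch b, 30.89%, lay between 25.45% and 38.3% under 16 alternatives, within its wide SD over libraries of 10.56. Leaving out a library cannot move a mean by its SD. Keeping every barcode, complete linkage and equally weighted cells gave the same split. With cells thinned to 500 UMIs and clustered again, the smaller side held 254 cells, and 6421 cells had a side in both this tree and the main one. The filter that kept every barcode changed nothing, since no barcode fell under the minimum. Of the values for named genes under alternatives, 441 kept direction and threshold and 2 missed the threshold, 1 had no adjusted p in DESeq2, and 14 more have no value because the gene was not tested, although its cluster had a match, 7 of them with sums of at least 10 cells. The named genes were chosen in the same data as large changes past the threshold, so that most stayed past it could be foreseen. Keeping every barcode, and for the branches complete linkage and equally weighted cells, repeated the main fit. The size of the fold change of most named genes moved by over 1.5 times under some setting. Causes were not tested unless stated. Clusters without a match, and clusters 10 and 11 without library 1, gave no value. Depth may limit the small clusters and the genes of few UMIs most, which was not tested. Of the simulated 4-fold changes, 10%, 40% and 50% were recovered in clusters 11, 8 and 9, against 67% in cluster 4 and 75% in cluster 1.

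Cluster 3 held 7.38% of the cells at resolution 0.8, 21.7% without high doublet scores and 21.5% at a minimum of 1000 UMIs. Cluster 5 held 21.1% with all UMIs, 20.7% without high doublet scores and 23.5% at the 1000 UMI minimum. Without thinning, the difference in genes per cell, branch b minus branch a, was 806, and clusters 1 to 8 lay -35.0%, -21.4%, -14.0%, 8.73%, 29.8%, 67.0%, 3.28% and -38.4% from their mean. Clusters 5, 7 and 8, which lay on 1 side of the mean in each library when thinned, turned direction, and clusters 1, 2 and 6, which did not, changed sign too. Thinned to 500 UMIs, clusters 4 and 8 lay 9.80% and 2.65% above it. Library 1 alone had an adjusted Rand index of 0.494 at resolution 0.3, and the mean correlation of libraries was 0.972 with no filter on genes.

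The branch comparison called 2860 genes without the replicate block and 3387 at a 1.5-fold threshold, and between 3425 and 5812 with 1 library left out. Without the block, clusters 1, 2, 3, 8 and 9 had 298, 487, 1036, 436 and 448 calls, and the block changed no other count by over 1.5 times. At the 1.5-fold threshold, clusters 1, 2, 3, 5, 8 and 9 had 321, 570, 821, 1768, 499 and 501. Against the summed rest, clusters 1, 2, 3 and 8 had 3627, 3439, 4842 and 1480. At a minimum of 1000 UMIs, clusters 1, 3 and 9 had 2231, 4030 and 1676. With all UMIs, clusters 5, 9, 10 and 11 had 4678, 1660, 3289 and 437. With 15 components, clusters 2 and 9 had 2156 and 1212. Cluster 1 had 635 calls with the DESeq2 Wald test, cluster 3 had 1001 at resolution 0.8, and cluster 8 had 580 with sums of at least 10 cells. With 1 library left out, the counts ranged from 280 to 796 for cluster 1, 476 to 1294 for cluster 2, 939 to 1976 for cluster 3, 3045 to 4994 for cluster 4, 4522 to 6405 for cluster 6, 1620 to 3338 for cluster 7, 238 to 687 for cluster 8 and 290 to 802 for cluster 9. DESeq2 size factors moved the median log2 fold change over all genes by between -0.25 in cluster 3 and 0.23 in cluster 4, and the summed rest by up to -0.52 in cluster 6. Changes in a cluster are relative to these shifts.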

Other observations

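The tests in this part were chosen after the result was seen, except the share of cells on the same side of the tree and the ratio within bins of depth, whose bounds were set before. In profile correlation across genes, cluster 10 was nearest to cluster 7 in each of the 3 libraries, at 0.844, 0.723 and 0.549. Cluster 11 was nearest to cluster 1 in each, though in library 3 by 0.525 against 0.522 for cluster 3 from 11 cells. Cluster 9 had no such partner, being nearest to cluster 1 in library 1 and to cluster 3 in libraries 2 and 3. UMIs were most concentrated in cluster 10, where the 10 most abundant genes took 12.4% ± 0.351 of the UMIs (SD, n = 3), and least in cluster 4, where they took 3.48% ± 0.757.

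Pairwise tests with edgeR called 270 genes between clusters 1 and 2 and 201 between clusters 1 and 8, and 7139 between clusters 3 and 6. These counts are no measure of likeness, since they also follow depth. The cluster 8 sums held 19777 and 27109 held-back UMIs in libraries 2 and 3, and cluster 1 correlated at 0.862 with cluster 8, below its 0.922 with cluster 2. Cluster 6 was not a unit in several alternatives. At resolution 0.8 it parted into 374 and 285 cells, and with all UMIs 380 of its cells joined 641 cells of cluster 5 while 269 formed a cluster apart, with 79, 59 and 131 of them in libraries 1, 2 and 3.

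Cells of branch b held more UMIs than those of branch a. If depth set the cells apart, the neighbours of branch b cells at 500 UMIs per cell would be mixed. Of those neighbours, 88.5% ± 3.2 (SD, n = 3) were branch b cells, whose share of all cells was 26.0%. The thinned cells also held UMIs that had made the clusters, so a high value was partly set in advance. The test therefore does not settle whether depth sets the cells apart. Whether depth sets the place of the first split stays open too. With every cell at 500 UMIs and clustered again, 75.6% of the cells were on the same side, where 71.9% would be with all on the larger side, because the split then set apart 254 cells, 246 of them of cluster 6. Cells of another stem tissue may contribute to branch b, but 0 features had a name other than their ID, so no marker could be looked up.

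Over the cells of the 3 libraries together, cluster 6 had the highest median, 2643 UMIs, but it led in library 1 alone, at 4604. Cluster 5 was deeper than cluster 6 in library 2, at 2642 against 2529, and in library 3, at 1981 against 1869. Doublets of other clusters would lie between their parents. Of the genes called higher in cluster 6, 14.4% were higher than in each other of the 9 clusters compared in pairwise tests. That share argues against cluster 6 being made up wholly of doublets of the compared clusters. It cannot show whether some doublets raise the median of cluster 6, since the pairwise tests take the libraries together and do not look at depth. The smallest clusters were not in these tests, so doublets with their cells stay open. The share ran from 1.3% in cluster 3 to 20.1% in cluster 7 and may follow depth, which was not tested. Its size therefore does not measure how many doublets there are. A few abundant genes taking most of the UMIs is argued against as well, since the 10 most abundant genes took a share that differed by -3.28 ± 1.12 percentage points (SD, n = 3) from the mean of the other clusters. No biological explanation was tested, since the labels give 1 group.

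Cluster 1 made up a larger share of library 1 than of the other libraries. Within 3 bins of UMIs per cell, the share in library 1 was at least 1.86 times the mean of libraries 2 and 3, which argues against depth per cell. The alignment of the libraries stays open: the ratio was 2.92 with libraries ignored in scaling, and 1.85 with Seurat integration, but there the nearest cluster overlapped cluster 1 by a Jaccard index of only 0.367. No biological explanation was tested, since the labels give 1 group.

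Other splits of the 6 sums into 3 and 3 were counted for the branch comparison and for clusters 1 to 8 against the summed rest of their libraries. In each, 1 of the 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real split called 5082 genes between the branches and 3627, 3439, 4842, 6402, 2805, 6683, 2234 and 1480 for clusters 1 to 8, and the highest other split called 0 with edgeR in each. Each other split has sums of both groups on each side, so the difference between the groups adds to its spread. That these splits called no gene could be foreseen and does not weigh on chance. The groups were also made by clustering the same cells. The sums are paired by library, and 4 of the 10 splits, the real one included, part each pair. At an unadjusted p under 0.05, the highest other of these had 67 genes for the branches and at most 195, for cluster 7. The 6 splits that leave a pair on 1 side reached 195 for the branches and at most 734, for cluster 7.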
